A study of Oryza sativa with 12 samples.

How the data were processed

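RNA from dissected rice inflorescence meristems, sampled at an early inflorescence stage with a few bracts attached, was measured on 12 Affymetrix arrays. There were 4 genotypes with 3 arrays each: wild type (WT), fon2-3, asp1-10 and the double mutant fon2-3 asp1-fe. The plants grew outdoors in pots, and the meristems were dissected under a microscope and frozen in liquid nitrogen. Biotin-labelled sense-strand DNA made from total RNA was hybridised to 1-colour arrays, and per the labels the authors processed the signals with Affymetrix Expression Console 1.3. Background correction, normalization, the summarisation method and the log base are not given in the sources used here. The deposited values were taken as log2 signals because of their range, and nothing in them contradicted that unit. Array medians ran from 5.51 to 5.60 without identical quartiles, so the arrays lay on a common scale but were not exactly quantile-normalized over these probes. All log2 changes below assume base 2.

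The table held 54922 probes, of which 7300 shared their values on every array with another probe, leaving 50208 distinct profiles. A probe-to-gene table listed a gene for 16269 probes, with 1 symbol for 15829 and several for 440. The remaining 38653 probes had no gene there and entered the counts of probes only. Of 15140 genes with a probe, 1729 carried a name other than a locus or clone number. For the 627 genes with several probes, the probe with the highest mean over the 12 arrays stood for the gene. No genome build was stated, so no positions are given. Gene order for tests on neighbouring genes came from the rice gene table of the assembly ASM3414082v1. FON2 and ASP1, the mutated genes, had no probe under these names and were not analysed here under them.

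A linear model with 1 mean per genotype was fitted to all 12 arrays with limma 3.58.1 (lmFit, eBayes) under R 4.3.3. It had 8 residual degrees of freedom and 3.22 prior degrees of freedom. Each mutant was compared with WT, the double mutant with each single-mutant line, and asp1-10 with fon2-3. Additivity was tested as the double mutant plus WT minus both single mutants. An F-test compared the 4 genotypes together. Tests were two-sided, and p-values were adjusted within a comparison by the Benjamini-Hochberg method with a threshold of 0.05. A gene is said to have risen, fallen or changed where its adjusted p was below that threshold. These p-values measure only the spread between these samples. An exact permutation test of 3 arrays against 3 cannot give a two-sided p below 0.1, so single genes were not tested that way. The number of arrays, 3 per genotype, limits the precision.

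The tests, the gene lists, the rule for named genes and the alternatives were set before the data were examined, except where a later choice is stated. In each comparison with WT the rule named a core set (FON1, WOX4, ASPR1, ASPR2 and OSH1 of those with a probe), the 10 largest rises and 10 largest falls among named genes past the threshold with no overlap between mutant and WT arrays, and up to 3 called members of each list. Where fewer than 5 such genes passed, the 5 with the smallest p were given as values. There were 25 lists, of which 21 had at least 3 measured genes and were tested. They covered the CLAVATA and WUSCHEL pathway, KNOX and BELL homeobox genes, inflorescence architecture, MADS-box, SPL, YABBY and TCP factors, Aux/IAA repressors, other auxin genes, cytokinin, gibberellin and jasmonate genes, photosynthesis, anther and tapetum, vascular and secondary wall, cell cycle, cytosolic ribosomal proteins, heat shock and chaperones, the circadian clock, defence, and dehydration with late embryogenesis abundant proteins. TOPLESS corepressors and flowering signals had 1 or 2 measured genes and got no test. Histones and transposable elements had none. The lists had been written as description patterns, and these were rewritten as symbol patterns after the gene names, but no test, had been seen. Of the listed members 56 had no match by symbol on the chromosome of their listed locus. Among them ASPR1, ASPR2, RCN1, IDS1 and BOP1 each had 1 gene of that symbol on another chromosome. ASPR1 and ASPR2 entered their list through the symbol pattern.

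Lists were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the 21 lists of a comparison, and again with an estimated correlation. The fry test asks instead whether a list's genes move one way on balance. Other alternatives were cyclic loess between arrays, centring each array on its median, leaving out dim probes (highest genotype mean below 5.55, the median of all values), fitting only the groups compared, a variance trend with a robust prior, array weights, replicate number as a block, an absolute log2 change of at least 1, 1 probe per named gene, and leaving out each array in turn. A genotype mean below 5.55 was not shown to exceed background, so a fold change from or to it can be too small. Counting identical probe profiles once was added after seeing the data, as were the block and the left-out arrays for the correlations and covariances between mutants. Correlations of changes between mutants were computed over genes, which are not independent replicates. They were set against 100 simulations of unchanged groups that shared the WT arrays, with genes drawn independently of each other.

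The model was checked on simulated data in which 200 of the 54922 probes had been changed. It recovered between 61.2% and 77.6% of changes of 1 log2 unit in the comparisons of 2 genotypes, 25.4% for additivity, and at least 86.6% of changes of 2 log2 units, with 5 to 14 false calls per comparison. In a simulated list test, the 1 shifted list was called and 0 unchanged lists were. Both checks drew normal noise independently for each probe or gene with the fitted variances, and without an outlying array. The rates therefore hold under the assumptions of the model and do not carry over to correlated genes or an outlying array. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.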

Results

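Gene expression was measured in dissected inflorescence meristems of rice on 12 arrays, with 3 each for WT, the fon2-3 mutant, the asp1-10 mutant and the double mutant fon2-3 asp1-fe. FON2 encodes a CLAVATA3-like peptide that limits meristem size, and ASP1 encodes a TOPLESS-like transcriptional corepressor. The double mutant carries another asp1 allele than the single mutant, so a difference between these lines can come from the allele as well as from fon2-3. Array medians lay between 5.51 and 5.60 on the log2 scale, and Pearson correlations between arrays over all probes ran from 0.962 to 0.986. The first principal component, with 32.8% of the variance, parted the 3 WT arrays from 7 of the 9 mutant arrays, with asp1-10 replicates 1 and 2 between them. Array 3 of asp1-10 stood apart from its own group: its mean correlation was 0.975 with the other asp1-10 arrays and 0.983 with the fon2-3 arrays.

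**Figure D1:**
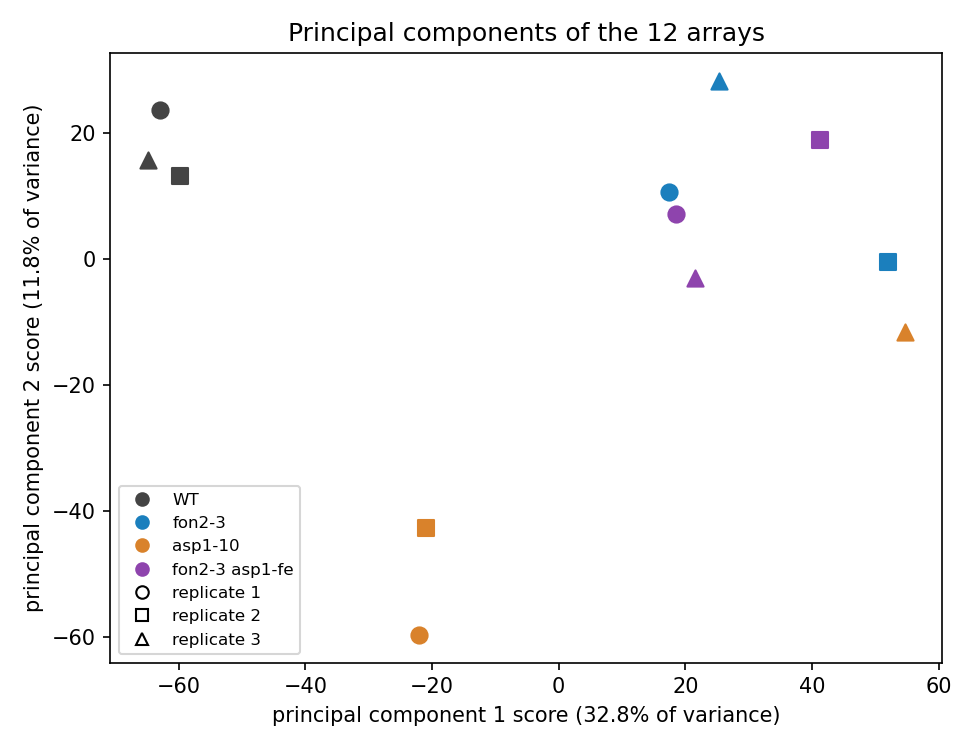
Scores of the 12 arrays on principal components 1 (32.8% of variance) and 2 (11.8%), with colours for genotypes and marker shapes for replicate numbers. WT arrays have component 1 scores between -64.8 and -59.9, and asp1-10 replicate 3, at 54.6, lies beside fon2-3 replicate 2, at 51.9.

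Some genes varied widely between arrays of the same genotype. PDC1, a pyruvate decarboxylase of fermentation, read 11.72 and 11.46 in asp1-10 replicates 1 and 2 and lay lower by 6.23 log2 units in replicate 3 (difference -6.23), and it read 6.02 in WT replicate 1 against 11.58 and 10.94 in the other WT arrays. NSHB2, a non-symbiotic haemoglobin gene, and GAPC3, a cytosolic glyceraldehyde-3-phosphate dehydrogenase gene, were also lower in those 2 arrays than in the others of their genotype, NSHB2 at 4.36 in asp1-10 replicate 3 and 4.20 in WT replicate 1. NSHB2 was low in most fon2-3 and double mutant arrays as well, at 4.95, 4.03 and 4.84 in fon2-3 and 6.03, 4.07 and 3.82 in the double mutant, whereas PDC1 varied there, at 9.55, 5.81 and 7.755 in fon2-3 and 9.505, 6.05 and 5.49 in the double mutant. LHY, a morning gene of the circadian clock, read 6.88, 9.83 and 6.79 in the fon2-3 arrays and 5.84, 6.34 and 10.16 in the double mutant arrays. OsPCL1, a clock gene of the opposite phase, read 5.19, 3.45 and 6.80 in fon2-3 and 6.25, 6.26 and 2.83 in the double mutant. The labels give no batch, date or hour, so no value could be recomputed within batches.

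**Figure D2:**
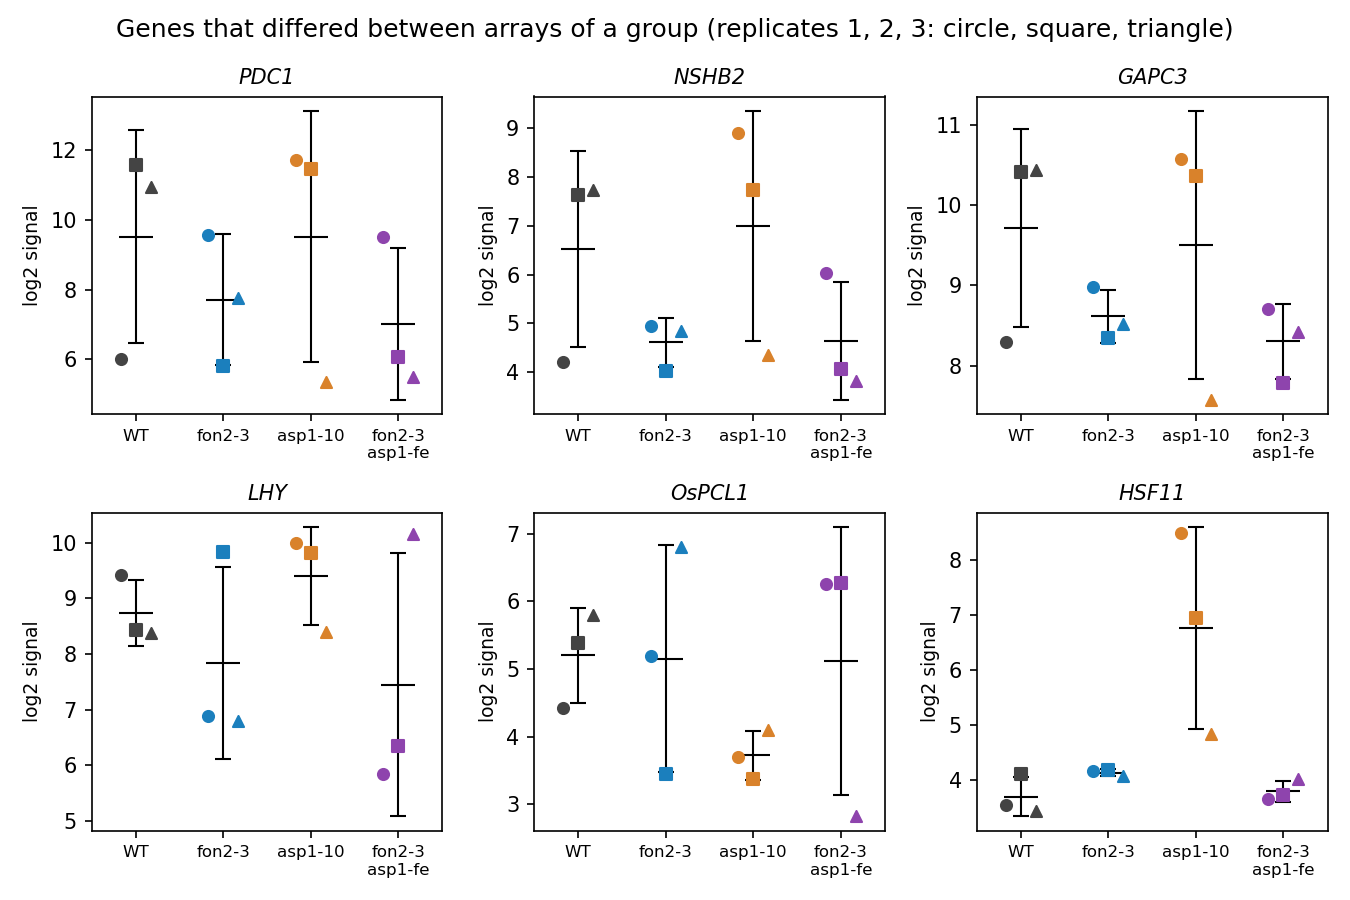
Log2 signal of 6 genes on each array by genotype, with the mean and SD of 3 arrays as bars and marker shapes for replicate numbers. PDC1, NSHB2 and GAPC3 are lower in asp1-10 replicate 3 and WT replicate 1 than in the other arrays of these genotypes, PDC1 varies between fon2-3 and double mutant arrays too, and LHY and OsPCL1 differ in opposite directions between arrays of fon2-3 and of the double mutant.

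The comparison of fon2-3 with WT addressed which genes change when the FON2 signal is impaired. OsGRF1, a growth-regulating transcription factor, rose 3.91-fold (log2 change 1.97, SE 0.394, n = 3 per group, adjusted p = 0.0259), and CYCD2-2, a D-type cyclin, rose 3.68-fold (SE 0.273 in log2, adjusted p = 0.0159). MOF1, a MYB-type gene of spikelet determinacy, rose 3.57-fold, and PCF5, a TCP-type factor, rose 3.46-fold. DOF1, HOX4, CYP724B1 (brassinosteroid synthesis), AP25, OsORC4 (replication origin recognition) and ARF3 (an auxin response factor) completed the 10 largest rises, which ended at 2.48-fold. Among the falls OsWRKY71, a WRKY factor of defence, was 6.28-fold lower (log2 change -2.65, SE 0.517, adjusted p = 0.024), and OsNAC6, a stress-responsive NAC factor, 5.77-fold lower. SAT1, OsTIP2;2 and AQP (aquaporins of the vacuole membrane), BZIP52, OsPSY1 (phytoene synthase of carotenoid synthesis), OEE3 (photosystem II), XDH (xanthine dehydrogenase) and IVD (leucine breakdown) fell between 2.84-fold and 5.40-fold.

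Of the 5 core genes 0 passed the test in fon2-3. FON1, the CLAVATA1-like receptor kinase of the same pathway, read 6.83 (SD 0.717) against 6.08 (SD 0.565) in WT with adjusted p = 0.272, and WOX4, a WUSCHEL-type homeobox gene, differed by -0.26 with adjusted p = 0.199. Of the TOPLESS corepressors, ASPR2 read 8.96 (SD 0.532) against 8.75 (SD 0.0205), adjusted p = 0.62, and ASPR1 11.29 against 11.34, adjusted p = 0.779. The KNOX and BELL list had 7 measured genes: OSH1, OSH15, OSH71, OSH45, HOS58, HOS59 and HOS66. Its members qSH1 and SH5 had no match by symbol. OSH45, HOS58, HOS59 and HOS66 were not among the genes named for the list and entered through its symbol pattern. The name of the list therefore does not show that a BELL gene was measured. Whether all 7 genes act in meristem maintenance was not checked. Of these, OSH71 rose 2.10-fold and OSH15 2.08-fold, 5 did not pass, and 3 rose when adjusted over the list alone. OSH1 was 0.68 log2 units above WT (adjusted p = 0.108). Photosynthesis genes were lower as a list (mean log2 change -0.729, camera adjusted p = 0.0243; adjusted p = 0.473 with an estimated correlation). OEE3 and PSAH, a photosystem I subunit, fell, the same 2 when adjusted over the list alone, while PSAG, PSB28, CAB1R and CAB2R did not pass. That list's call ended with fry (adjusted p = 0.0537), with cyclic loess (0.0699), without WT replicate 1 (0.0739) and without fon2-3 replicate 3 (0.103).

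Hormone genes moved in small numbers in fon2-3. Of 19 Aux/IAA repressors, IAA2, IAA7 and IAA17 rose by 0.97, 0.85 and 0.56 log2 units, and adjusted over the list alone 4 rose and 1 fell. Of 24 other auxin genes, ARF3 rose and SAUR39, a dim probe, fell, against 8 and 2 adjusted over the list alone. Cytokinin genes had 4 rises among 24, with OsRR1, a response regulator, up by 1.09 and HK5, a receptor, up by 0.98, and 1 fall, LOGL3 at -1.14; adjusted over the list alone 4 rose and 2 fell. GA20OX3, a gibberellin 20-oxidase, fell by 0.70 and was the 1 call among 3 gibberellin genes either way. Of 16 cell cycle genes CYCD2-2 and CYCD5-3 rose, and adjusted over the list alone 4 rose and 1 fell. SPL6 (of 6 SPL factors, 2 adjusted over the list alone), PCF5 (of 6 TCP factors, 2 adjusted over the list alone) and CESA4 (of 18 wall genes, 1 adjusted over the list alone) rose, and MADS57, a dim probe (of 21 MADS-box factors, 2 adjusted over the list alone), and PRR37 (of 6 clock genes, 1 adjusted over the list alone) fell. Camera called none of these lists, with adjusted p from 0.168 to 0.961 over the 20 lists other than photosynthesis. With fry the TCP and cytokinin lists were higher in fon2-3 (adjusted p = 0.00291 each).

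In limma 2866 probes differed between fon2-3 and WT, 2077 higher and 789 lower, and among genes 592 rose and 274 fell. The count moved widely when single arrays were left out. It was 1 without fon2-3 replicate 2, 4 without WT replicate 1, 334 without WT replicate 3 and 839 without fon2-3 replicate 3. It was 1342 without WT replicate 2, 1796 without fon2-3 replicate 1 and 4554 without asp1-10 replicate 3. Lost calls in a fit of fewer arrays do not by themselves show that the changes came from the array left out. Of the 36 named genes called here, the calls kept were 0, 0, 6, 14, 23, 25 and 36 with the same arrays left out in turn, and all kept their direction.

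The comparison of asp1-10 with WT addressed which genes depend on the ASP1 corepressor. ASPR2 (LOC4327709), an ASP1-related corepressor gene of the TOPLESS family, rose 4.27-fold, from 8.75 (SD 0.0205) to 10.85 (SD 0.171, n = 3 each, adjusted p = 0.00698), and ASPR1 read 11.36 against 11.34 (adjusted p = 0.968). The names follow the gene table; the lists fixed beforehand gave the names ASPR1 and ASPR2 to these 2 loci the other way round, so it is the gene LOC4327709 that rose, whichever name it carries. MADS34, a SEPALLATA-like gene of panicle and spikelet development, rose 6.83-fold (SE 0.598 in log2, adjusted p = 0.0417), and APO2, the rice LEAFY gene, rose 3.03-fold (SE 0.244 in log2, adjusted p = 0.0152). DL, a YABBY gene of carpel identity and leaf midrib formation, fell 2.8-fold, from 10.19 (SD 0.164) to 8.71 (SD 0.248), with adjusted p = 0.00805. PRR37, a clock and heading-date gene, fell by 1.04 log2 units with the same adjusted p.

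Other rises in asp1-10 were the heat-stress factor HSF11 (8.39-fold from a dim 3.695 in WT, SD 1.84 between the asp1-10 arrays), the small heat shock gene HSP17.4 (6.55-fold), DOF1 (3.45-fold), CYCD2-2 (2.63-fold), CYP724B1 (2.61-fold), OSH71 (2.46-fold) and OsAPY3, an apyrase (2.38-fold). HSF11 read 8.50 and 6.96 in replicates 1 and 2 and 4.84 in replicate 3, the array that stood apart. Besides DL and PRR37, the falls comprised OsPSY1 (3.23-fold), GA20OX3 (2.34-fold), PSAH (2.31-fold), OsHAP3I (a dim probe), OsRSH3 (plastid stringent response), MHZ4 (abscisic acid synthesis), RRF (ribosome recycling) and SSRP1-B (a histone chaperone subunit), the last 4 between 2.05-fold and 2.14-fold. CYCD6-1 rose 1.91-fold and CYCB1-1, a mitotic cyclin, fell 1.68-fold. FON1 (6.96, SD 0.213), WOX4 (5.87, SD 0.0753) and OSH1 (8.51, SD 0.15) did not pass, with adjusted p of 0.255, 0.596 and 0.0947.

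The 7 measured genes of the KNOX and BELL list were higher as a list in asp1-10 (mean log2 change 0.736, camera adjusted p = 0.0106, and 0.63 with an estimated correlation). All 7 had a positive change, OSH71 and OSH15 rose 2.46-fold and 2.22-fold, 5 did not pass, and 4 rose when adjusted over the list alone. The camera call held with each of the 12 arrays left out, with adjusted p from 0.003 to 0.042. Of 6 inflorescence architecture genes APO2 rose and DL fell, with 1 and 1 adjusted over the list alone, and LAX1, FZP, NL1 and PLA1 did not pass. Heat shock genes had 2 rises among 22 and 5 adjusted over the list alone. Cell cycle genes had 2 rises and 1 fall among 16, against 3 and 2 adjusted over the list alone, and other auxin genes had 0 of 24 called, against 7 rises and 1 fall adjusted over the list alone. Anther and tapetum genes had 0 of 6 called and 2 rises adjusted over the list alone. Single calls were MADS34 (of 21 MADS-box factors), SPL6 (of 6), IAA17 (of 19 Aux/IAA repressors), HK5 (of 24 cytokinin genes) and CESA4 (of 18 wall genes) as rises, and GA20OX3 (of 3), PSAH (of 6 photosynthesis genes) and PRR37 (of 6) as falls. Adjusted over the list alone, these lists had 1 rise and 1 fall, 2 rises, 2 rises and 2 falls, 2 rises, 1 rise, 1 fall, 2 falls and 1 fall. Camera adjusted p ran from 0.143 to 0.915 over the 20 lists other than KNOX and BELL.

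**Figure D3:**
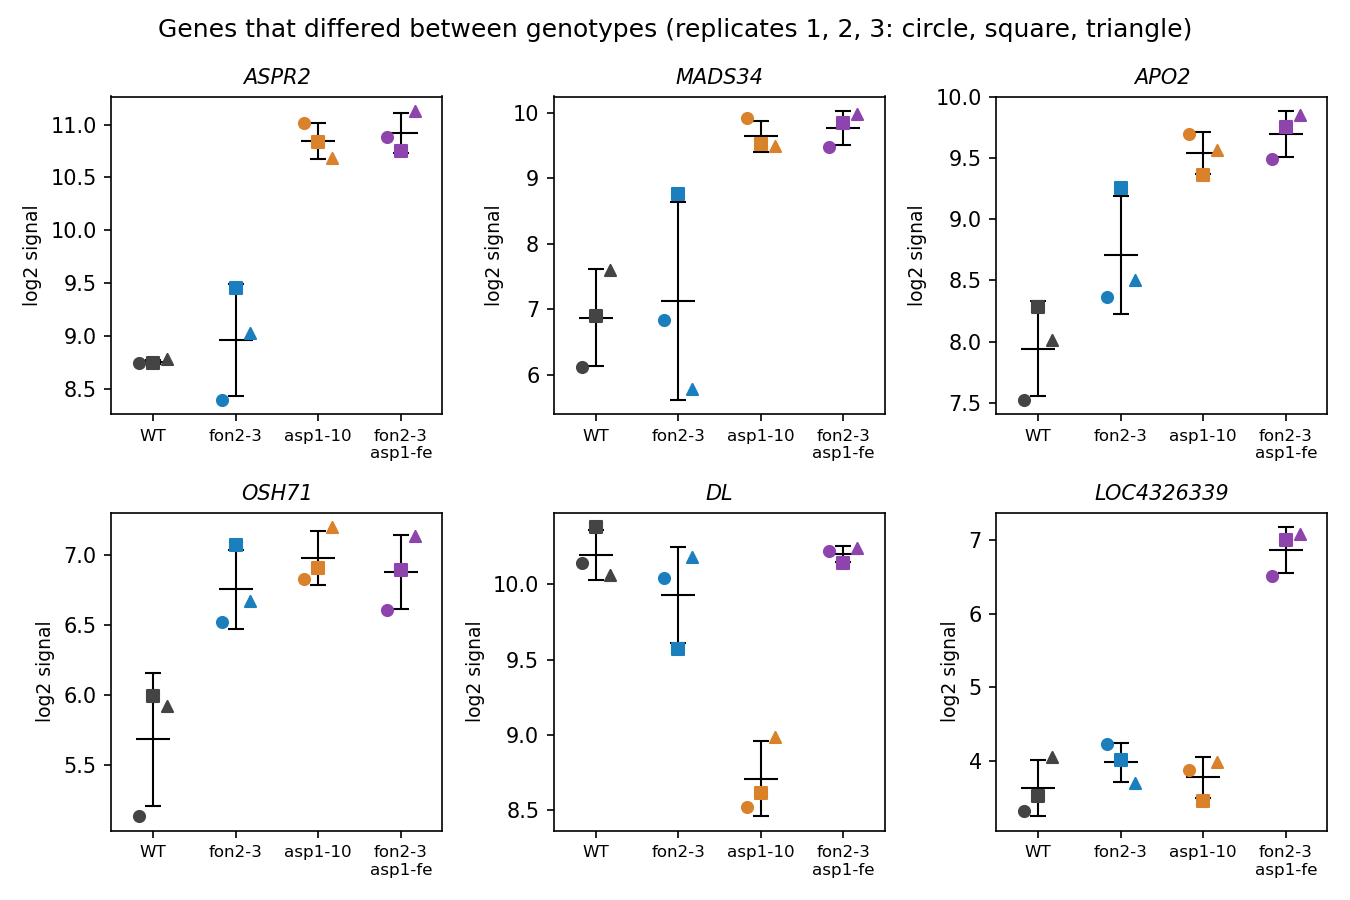
Log2 signal of 6 genes on each array by genotype, with the mean and SD of 3 arrays as bars and marker shapes for replicate numbers. ASPR2, MADS34 and APO2 are higher in both lines with an asp1 allele than in WT, DL is low in asp1-10 at 8.71, and LOC4326339 is high in the double mutant at 6.86.

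For asp1-10 against WT 1157 probes differed in limma, 754 higher and 403 lower, and 212 genes rose and 156 fell. The number was 163 without WT replicate 1, 215 without asp1-10 replicate 3, 271 without WT replicate 3, 390 without WT replicate 2, 541 without asp1-10 replicate 1 and 743 without double mutant replicate 1, and it was 2 when only the 6 arrays compared were fitted. Of 27 named genes called here, 5, 9, 11, 17, 17 and 20 kept the call with those arrays left out in turn and 1 in the fit of 6 arrays; that 1 was ASPR2, whose adjusted p stayed past the threshold under every alternative run for it.

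The comparison of the double mutant with WT addressed the combined effect of fon2-3 and asp1-fe. MADS34 rose 7.42-fold (SE 0.598 in log2, n = 3 per group, adjusted p = 0.0305), HOX4, a homeodomain-leucine zipper factor, 5.92-fold (SE 0.375 in log2, adjusted p = 0.0137) and MOF1 4.58-fold (SE 0.26 in log2, adjusted p = 0.00974). ASPR2 rose 4.49-fold to 10.92 (SD 0.194, adjusted p = 0.00466). CYP724B1 (4.85-fold), OsGRF1 (4.75-fold), DOF1 (4.28-fold), CYCD2-2 (4.10-fold), OsABCG36, an ABC transporter (3.40-fold), and APO2 (3.38-fold) were the other large rises. OSH1, the KNOX gene that marks meristem cells, rose 2.25-fold (adjusted p = 0.0288). DL read 10.20 (SD 0.0525) against 10.19 in WT (adjusted p = 0.988).

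Falls in the double mutant were led by OsTIP2;2 (4.44-fold), OsPSY1 (4.05-fold), BZIP52 (3.95-fold), OEE3 (3.63-fold) and XDH (3.24-fold). They included OsEGY2, a plastid protease (2.90-fold), IVD (2.53-fold), OsSWEET2a, a sugar transporter (2.45-fold), OsNOL, a chlorophyll b reductase (2.29-fold), and GA20OX3 (2.28-fold). FON1, WOX4 and ASPR1 differed from WT by 0.67, -0.08 and 0.10, with adjusted p of 0.356, 0.73 and 0.586.

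The 7 measured genes of the KNOX and BELL list were higher as a list in the double mutant (mean log2 change 0.746, camera adjusted p = 0.0275, and 0.313 with an estimated correlation). OSH15, OSH71 and OSH1 rose by 1.34, 1.20 and 1.17 log2 units, 4 of 7 did not pass, and 4 rose when adjusted over the list alone. The call ended without WT replicate 1 (0.0636), double mutant replicate 2 (0.0769) or double mutant replicate 3 (0.0804). Among the 24 auxin synthesis, transport and response genes 5 rose, with ARF3 (1.48), ARF14 (1.21) and the ARF2 gene LOC4325895 (1.19) the largest, and adjusted over the list alone 7 rose and 2 fell. Their mean was 0.301 (camera adjusted p = 0.0393; adjusted p = 0.313 with an estimated correlation), a call that ended without WT replicate 1 (0.0636), WT replicate 2 (0.0647), double mutant replicate 2 (0.094) or double mutant replicate 3 (0.0536). Cytosolic ribosomal protein genes were all higher, by a mean of 0.337 (camera adjusted p = 0.0254; adjusted p = 0.425 with an estimated correlation), with 0 of 9 past the test over all probes and 3 rises adjusted over the list alone. Photosynthesis genes were lower (mean -0.667, camera adjusted p = 0.0275; adjusted p = 0.313 with an estimated correlation), with falls of OEE3 and PSAH by either adjustment, the other 4 not passing. Without WT replicate 1 or double mutant replicate 2 the adjusted p was 0.0636 or 0.094 for the ribosomal list, whose mean was 0.21 without the latter array, and 0.0972 or 0.0769 for photosynthesis. With fry the ribosomal list had adjusted p = 0.0564.

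Other groups had fewer calls in the double mutant. IAA2, IAA7 and IAA17 rose among 19 Aux/IAA repressors by 1.38, 0.80 and 0.58 log2 units, 3 also adjusted over the list alone. SPL7 and SPL6 rose among 6 SPL factors and CYCD2-2 and CYCD5-3 among 16 cell cycle genes, with 2 and 4 adjusted over the list alone. OsRR1 and HK5 rose among 24 cytokinin genes, with 3 adjusted over the list alone. APO2 rose and GA20OX3 fell as the 1 call of their lists by either adjustment, and 2 of 5 YABBY factors rose when adjusted over the list alone, against 0 over all probes. PCF5 (of 6 TCP factors; 3 adjusted over the list alone), CESA4 (of 18; 1) and OPR10, a dim probe (of 20 jasmonate genes; 1), rose, and PRR37 (of 6 clock genes; 2 adjusted over the list alone) fell. MADS34 rose and MADS57, a dim probe, fell among 21 MADS-box factors, the same counts adjusted over the list alone. Camera adjusted p was 0.0541 for the clock list (mean -0.508) and ran up to 0.974 over the 17 lists not called.

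**Figure D4:**
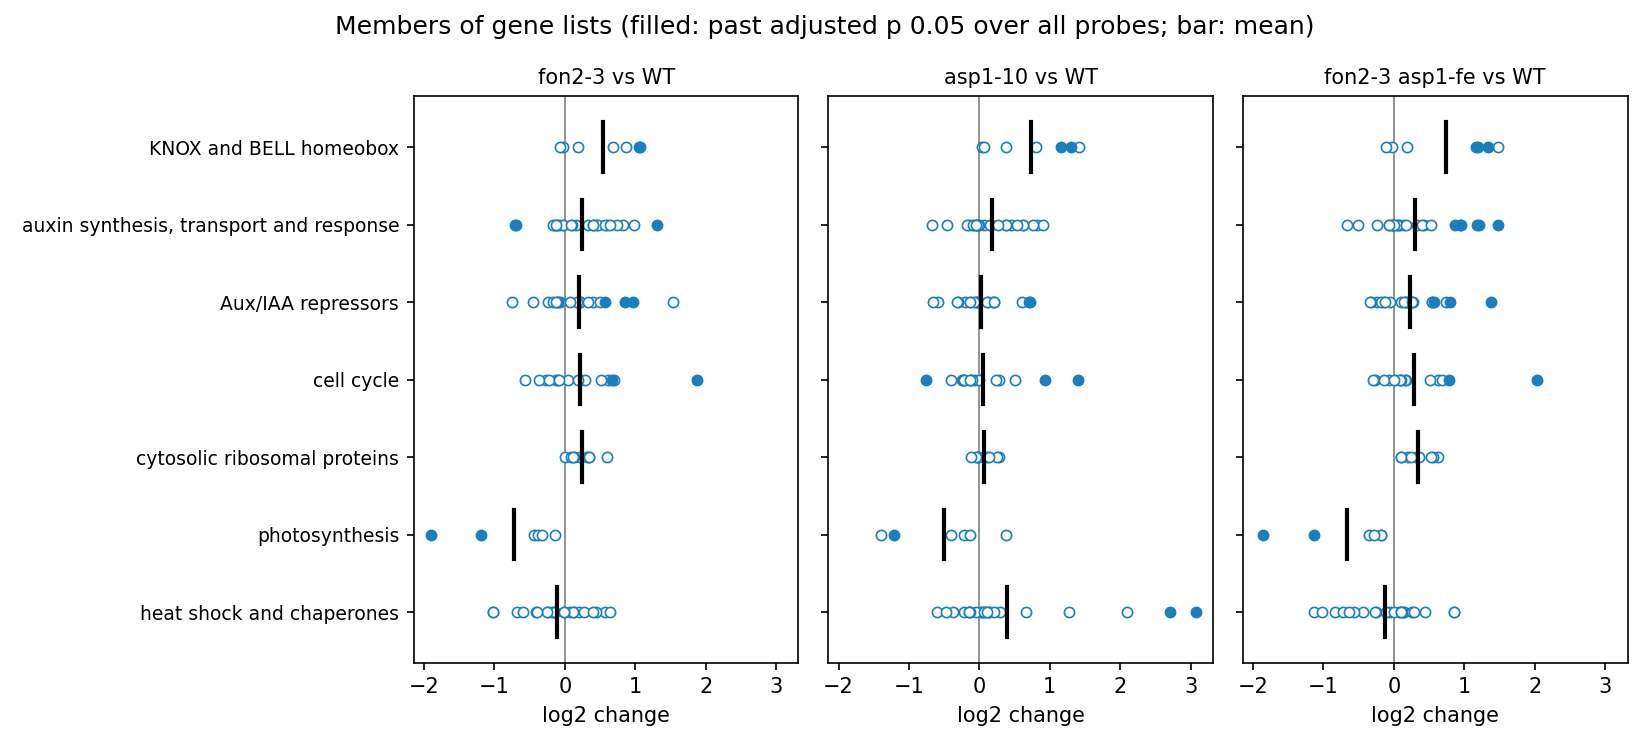
Log2 change of each member of 7 gene lists in each mutant against WT, filled where adjusted p over all probes was below 0.05, with a bar at the list's mean. The bars for the KNOX and BELL list lie at 0.54, 0.736 and 0.746, and those for photosynthesis at -0.729, -0.496 and -0.667.

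Between the double mutant and WT 2358 probes differed in limma, 1642 higher and 716 lower, and 438 genes rose and 248 fell. There were 18 without double mutant replicate 2, 236 without WT replicate 1, 334 without WT replicate 3, 461 without double mutant replicate 1, 992 without double mutant replicate 3, 1088 without WT replicate 2, 1567 without fon2-3 replicate 3 and 3998 without asp1-10 replicate 3. Of 40 named genes called here, 1, 10, 12, 18, 20, 28, 35 and 40 kept the call with those arrays left out in turn, in the same direction.

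Lists without a camera call against WT are given as mean log2 changes in fon2-3, asp1-10 and the double mutant, in that order. The CLAVATA and WUSCHEL genes, with 0 of 6 members past the test by either adjustment, had means of 0.0924, 0.202 and 0.204. The 6 were FON1, WOX4, FOS1, QHB, OsWOX6 and OsWOX7, while FON2, FCP1, FCP2 and TAB1 had no match by symbol. Just 2 of the 6 had a genotype mean that reached 5.55, so a change in the rest could have been missed. Means were 0.168, 0.46 and 0.361 for inflorescence architecture, -0.094, 0.047 and 0.0521 for MADS-box, 0.232, 0.244 and 0.337 for SPL, 0.196, -0.0128 and 0.455 for YABBY, and 0.527, 0.107 and 0.39 for TCP factors. In the single mutants, without a camera call, other auxin genes had means of 0.247 and 0.18 and ribosomal genes of 0.239 and 0.0607. Also without a call, the KNOX and BELL list had a mean of 0.54 in fon2-3 and photosynthesis genes of -0.496 in asp1-10. Hormone lists had means of 0.2, 0.0197 and 0.226 (Aux/IAA), 0.172, 0.0126 and 0.165 (cytokinin), -0.255, -0.499 and -0.305 (gibberellin), and 0.0759, 0.129 and 0.198 (jasmonate). For markers of other tissues they were 0.148, 0.188 and 0.0385 (anther and tapetum) and -0.0679, 0.0975 and -0.0763 (vascular and secondary wall). Cell cycle genes had 0.212, 0.0521 and 0.282, heat shock genes -0.105, 0.398 and -0.128, clock genes -0.334, -0.388 and -0.508, defence genes -0.125, -0.0613 and -0.0157, and dehydration genes -0.231, -0.0199 and -0.0756. The flowering signals Hd3a and Hd1 read 1.91 and 3.15 in fon2-3, 2.04 and 3.18 in asp1-10 and 1.84 and 3.37 in the double mutant against 2.31 and 3.44 in WT, and neither passed. Both genes lay below 5.55 in every genotype and were not shown to exceed background, so a change in them could have been missed. Median, mean and camera direction differed in sign for CLAVATA and WUSCHEL and jasmonate genes in fon2-3; for MADS-box, TCP, Aux/IAA, cytokinin, wall, cell cycle, ribosomal and dehydration genes in asp1-10; and for MADS-box and anther genes in the double mutant.

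The 3 mutants shared much of their difference from WT. Among genes, 95 rose and 65 fell in all 3 mutants. Such overlaps rest on calls whose number moved widely when single arrays were left out. Against WT, 1 probe was left in fon2-3 without fon2-3 replicate 2, and 18 in the double mutant without double mutant replicate 2. Of 592 genes risen in fon2-3 and 212 in asp1-10, 116 rose in both, where independent draws would share 8.29; of 274 and 156 fallen genes 85 were shared, where independent draws would share 2.82, and 1 gene changed in opposite directions. The double mutant shared 289 rises and 148 falls with fon2-3 and 133 rises and 85 falls with asp1-10, with 0 opposite changes in each pair. OSH71, OSH15, SPL6, IAA17, HK5, DOF1, CYCD2-2, CYP724B1 and CESA4 rose and OsPSY1, PSAH, GA20OX3 and PRR37 fell in all 3 mutants. Without asp1-10 replicate 3 all of these but HK5, DOF1, GA20OX3 and PRR37 lost the call in asp1-10, with adjusted p from 0.0569 (CYCD2-2) to 0.135 (CYP724B1). The genes that lost it kept their direction. Without that array OSH15 changed by 1.181 (1.153 with it) and IAA17 by 0.7162 (0.6985). OSH71 changed by 1.187 (1.297), CYP724B1 by 1.286 (1.386), CESA4 by 0.5703 (0.6058), SPL6 by 0.4651 (0.5536) and PSAH by -1.039 (-1.208). CYCD2-2 and OsPSY1 moved most, to 1.03 (1.394) and -1.252 (-1.69). In a fit of fewer arrays, lost calls alone do not show that these changes came from replicate 3. Over 15140 genes the log2 changes correlated at r = 0.701 between fon2-3 and asp1-10, 0.852 between fon2-3 and the double mutant and 0.715 between asp1-10 and the double mutant. Unchanged groups compared with the same WT arrays gave 0.5, 0.501 and 0.501 in simulations, and part of the overlap beyond independent draws can come from these shared arrays. Without asp1-10 replicate 3 the correlations of asp1-10 changes with those of fon2-3 and the double mutant were 0.481 and 0.505, near the 0.446 and 0.447 simulated for unchanged groups of the arrays kept. The covariances of these pairs, 0.0609 and 0.0639, lay above the highest simulated with independent genes, 0.0177 for each.

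The comparison of the double mutant with fon2-3 addressed what asp1-fe, an allele not measured alone, adds to fon2-3. ASPR2 rose 3.90-fold, from 8.96 (SD 0.532) to 10.92 (SD 0.194; SE 0.221, n = 3 per group, adjusted p = 0.0284). LOC4326339, a gene without a name, rose by 2.89 log2 units from 3.98 (SD 0.269) to 6.86 (SD 0.312; adjusted p = 0.00184), and its other probe rose too. Its signal outside the double mutant lay below 5.55, the limit for dim probes, and was not shown to exceed background, so the size is at best a lower limit. This gene read 3.77 in asp1-10 and 3.63 in WT, so its rise may belong to the asp1-fe allele or line instead of the loss of ASP1. LOC4325412 fell 3.04-fold from 7.53 (SD 0.286; adjusted p = 0.0382). LOC4344728 and LOC4337797, next by p, were 1.40 and 2.02 log2 units higher with adjusted p of 0.0811 and 0.183. LOC4344728, which has no other name in the gene table, read 10.21 (SD 0.261) in WT, 11.12 (SD 0.321) in fon2-3, 12.55 (SD 0.189) in asp1-10 and 12.51 (SD 0.115) in the double mutant, with adjusted p of 0.0267, 0.00263 and 0.00079 against WT. In limma 5 probes differed, 4 higher and 1 lower, of 3 genes (2964 probes at an unadjusted p below 0.05, where 2746.1 would be expected by chance). The count was 8 without fon2-3 replicate 2, 3 without fon2-3 replicate 1 or asp1-10 replicate 3, and 2 without WT replicate 1, WT replicate 2, fon2-3 replicate 3, asp1-10 replicate 1, asp1-10 replicate 2 or any of the double mutant replicates 1, 2 and 3. LOC4326339 passed under 16 of 16 alternatives. ASPR2 passed under 4, among the left-out arrays just without fon2-3 replicate 1 or 2, with adjusted p from 0.0104 to 0.5, while its rise stayed between 1.68 and 2.21 log2 units under all 16. LOC4325412 passed under 1, without WT replicate 3. Camera called 0 of 21 lists, with adjusted p from 0.161 to 0.958.

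The comparison of the double mutant with asp1-10 joined the effect of fon2-3 with that of the other asp1 allele. DL rose 2.82-fold, from 8.71 (SD 0.248) in asp1-10 to 10.20 (SD 0.0525) in the double mutant (SE 0.173, n = 3 per group, adjusted p = 0.0219). LOC4326339 rose from a dim 3.77 (SD 0.282) to 6.86 (adjusted p = 0.000591), so its 8.53-fold rise is at best a lower limit too. LOC4341024 rose by 0.97 log2 units from 5.69 (SD 0.196; adjusted p = 0.0219). LOC4337660 and LOC4340998, next by p, differed by 0.82 and -0.83 with adjusted p of 0.0928 and 0.14. In limma 8 probes differed, 7 higher and 1 lower, of 3 genes (4276 at an unadjusted p below 0.05). There were 100 without asp1-10 replicate 3, of which 26 were higher and 74 lower, 5 without asp1-10 replicate 2, and 4 without WT replicate 2, fon2-3 replicate 1, asp1-10 replicate 1 or any of the double mutant replicates 1, 2 and 3. LOC4326339 passed under 16 of 16 alternatives, DL under 6 and LOC4341024 under 5. Among the left-out arrays DL passed just without WT replicate 3, fon2-3 replicate 2 or 3, or asp1-10 replicate 3, and LOC4341024 without fon2-3 replicate 2 or asp1-10 replicate 2 or 3.

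Of the 21 lists camera called 5 between the double mutant and asp1-10, 4 higher and 1 lower. The 5 YABBY factors had a mean log2 difference of 0.468 (camera adjusted p = 0.000955; adjusted p = 0.139 with an estimated correlation), all of them positive, with OsYAB3 and OsYAB1 at 0.53 and 0.52. The 16 cell cycle genes had a mean of 0.23 (camera adjusted p = 0.000955; adjusted p = 0.139 with an estimated correlation), 14 of them positive. The 9 cytosolic ribosomal protein genes, all positive, had a mean of 0.276 (camera adjusted p = 0.000955; adjusted p = 0.42 with an estimated correlation), and 0.15 without double mutant replicate 2. Aux/IAA repressors had a mean of 0.207 (camera adjusted p = 0.0124; adjusted p = 0.222 with an estimated correlation), and that call ended without double mutant replicate 1 (0.0514). Heat shock and chaperone genes were lower, with a mean of -0.526 (camera adjusted p = 0.00303; adjusted p = 0.289 with an estimated correlation) and of -0.343 without asp1-10 replicate 1; HSF11 and HSP17.4 differed by -2.97 and -1.86, with adjusted p of 0.301 and 0.263. Over all probes 0 members of these 5 lists passed, and adjusted over the list alone 4 YABBY, 0 cell cycle, 0 ribosomal and 5 Aux/IAA genes rose, while 1 heat shock gene rose and 3 fell. With fry the ribosomal and heat shock lists had adjusted p = 0.151 each. The other 16 lists had camera adjusted p from 0.103 to 0.986.

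The comparison of the single mutants with each other tested whether their effects differed. ASPR2 was 3.70-fold higher in asp1-10 than in fon2-3 (log2 difference 1.89, SE 0.221, n = 3 per group, adjusted p = 0.0332). LOC4335004 fell by 2.02 log2 units to 4.50 (SD 0.35) and LOC4333361 by 1.32 to 6.41 (SD 0.212), each with adjusted p = 0.0213. LOC4344728 and LOC4325412 differed by 1.44 and -1.48 with adjusted p of 0.0514 each. An unnamed probe, chosen after its values were seen, read 4.72 (SD 0.0508) in asp1-10 and 4.31 (SD 0.28) in WT but 7.85 (SD 0.4) in fon2-3 and 8.07 (SD 0.119) in the double mutant (adjusted p = 0.000218 between the single mutants). In limma 6 probes differed, 1 higher and 5 lower in asp1-10, of 3 genes (5029 at an unadjusted p below 0.05). There were 300 without asp1-10 replicate 3 (153 higher and 147 lower), 21 without fon2-3 replicate 2 (14 higher and 7 lower), 10 without asp1-10 replicate 2 or double mutant replicate 3, and 1 without WT replicate 3, fon2-3 replicate 1, fon2-3 replicate 3 or asp1-10 replicate 1. Of 16 alternatives ASPR2 passed under 5, among the left-out arrays just without fon2-3 replicate 2, asp1-10 replicate 3 or double mutant replicate 3, while the difference stayed between 1.61 and 2.13 log2 units under all 16. LOC4335004 passed under 10 and LOC4333361 under 9, each losing the call without WT replicate 3, fon2-3 replicate 1 or 3, or asp1-10 replicate 1, and LOC4333361 also without double mutant replicate 1.

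TCP factors were lower in asp1-10 than in fon2-3 (mean -0.42, camera adjusted p = 0.0457; adjusted p = 0.404 with an estimated correlation), with PCF5, PCF6 and PCF7 at -0.95, -0.68 and -0.51. Heat shock genes were higher (mean 0.503, camera adjusted p = 0.0457; adjusted p = 0.445 with an estimated correlation), with HSP17.4 at 8.54 against 5.68 (adjusted p = 0.0514), and their mean was 0.319 without asp1-10 replicate 1. Over all probes 0 members of either list passed; adjusted over the list alone 3 TCP genes fell, and 4 heat shock genes rose and 1 fell. Leaving out single arrays ended the TCP call in 7 of 12 fits (WT replicate 3, fon2-3 replicates 1, 2 and 3, asp1-10 replicates 1 and 3, double mutant replicate 3) and the heat shock call in 5 of 12 (WT replicate 3, fon2-3 replicates 1, 2 and 3, asp1-10 replicate 1), with adjusted p up to 0.127 and 0.104. The heat shock list had adjusted p = 0.197 with fry, and the TCP list 0.0513 with dim probes left out. With replicate number as a block 0 lists were called. The other 19 lists had camera adjusted p from 0.126 to 0.76.

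Additivity was tested to ask whether the double mutant equals the sum of the single-mutant effects, taking both asp1 alleles to act alike. LOC4326339 read 3.98 and 3.77 in the single mutants, 3.63 in WT and 6.86 in the double mutant, a departure of 2.74 log2 units (SE 0.329, n = 3 per group, adjusted p = 0.0422). LOC4340483, LOC4341846 and LOC4344111 read higher in all 3 mutants than in WT, without adding up in the double mutant. LOC4341846 read 6.29 in WT, 6.92 in fon2-3, 7.23 in asp1-10 and 6.80 in the double mutant (departure -1.07, adjusted p = 0.0497). An upward shift of all 3 mutants away from WT would by itself give a downward departure, so a non-additive effect cannot be told apart from it. The departures of LOC4340483 and LOC4344111 were 2.46-fold and 2.78-fold downward, with adjusted p of 0.0422 and 0.0497. LOC4349417, next by p, departed by 3.21 with adjusted p = 0.0626. In limma 7 probes departed, 2 upward and 5 downward, of 4 genes (7114 at an unadjusted p below 0.05). There were 25 without asp1-10 replicate 2, 18 without WT replicate 2, 14 without asp1-10 replicate 3, 2 without fon2-3 replicate 3, and 1 without each of WT replicates 1 and 3, fon2-3 replicates 1 and 2, asp1-10 replicate 1 and double mutant replicates 1, 2 and 3. On the probes that stand for the genes, LOC4340483, LOC4326339, LOC4344111 and LOC4341846 passed under 5, 4, 2 and 1 of 15 alternatives. The other probe of LOC4326339, dim outside the double mutant, departed by 4.32 log2 units with adjusted p = 0.000317. Camera called 0 of 21 lists, with adjusted p from 0.223 to 0.99.

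The F-test over the 4 genotypes called 973 probes of 328 genes, against 11345 at an unadjusted p below 0.05. It called 2978 without asp1-10 replicate 3, 20, 261 and 53 without WT replicates 1, 2 and 3, 491, 492 and 357 without fon2-3 replicates 1, 2 and 3, 631 without asp1-10 replicate 1, and 374, 227 and 380 without double mutant replicates 1, 2 and 3.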

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

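Relabelling and tests of explanations were run for the results above. The relabelling tests and those of low oxygen, of strain variants and of array normalization were set before their results were seen. The other tests were chosen after the result was seen: both tests of a mislabelled array, and those of the hour of sampling, shared WT arrays, bract tissue, tissue or stage share, and a paralog.

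In each comparison of 2 genotypes the 6 arrays can be split in 10 ways, too few for a test. The rank of the real labels was 1 of 10 in each of the 6 comparisons, with at most 2, 3 and 4 probes under other labels for fon2-3, asp1-10 and the double mutant against WT, 4 for the double mutant against fon2-3, and 0 for the double mutant against asp1-10 and for asp1-10 against fon2-3. For the F-test the real labels ranked 1 of 100 draws, with 973 probes against at most 5. For additivity they ranked 3 of 100: 7 probes departed with the real labels, 1393 and 651 in the highest of the other draws, and 0 in 93 draws. These 2 draws each set all WT arrays and asp1-10 replicates 1 and 2, with 1 other array, against the remaining arrays, so they point to a structure of the samples, the known difference of the WT arrays from most mutant arrays, which such a draw carries into the additivity contrast.

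Replicate 3 of asp1-10 lay apart from replicates 1 and 2, and over probes that separate these from another genotype it lay nearer to the other mutants: the median position between the double mutant (0) and replicates 1 and 2 (1) was 0.142, against 0.214 for fon2-3 and 0.979 for WT. That position restates the correlations which prompted the test, so it does not bear on an exchange by itself. Marker genes, a test chosen after that result, were picked in fits that counted replicate 3 as asp1-10, but they also passed without it. ASPR2 in replicate 3 was 1.23 above the highest WT or fon2-3 array. LOC4326339 was 2.52 below the lowest double mutant array, and DL was 0.583 below the lowest array of the other genotypes. In limma without replicate 3, ASPR2 and DL still passed against WT (adjusted p = 0.0136 and 0.012). Of the probes chosen without it, however, 27.7% (against fon2-3) and 22% (against the double mutant) placed replicate 3 nearer to asp1-10. A difference in oxygen supply before freezing is not settled, as 7 low-oxygen genes not looked at before had a median difference of -0.356, lower than in all but 0.32% of random lists but short of the bound set beforehand. The hour of sampling is not settled either. The median absolute difference of the clock genes was 0.461, reached by 1.3% of random lists. Those lists were drawn from all genes without matching their variability. The clock genes LHY and OsPCL1 also differed widely between arrays of fon2-3 and of the double mutant, so such a difference does not set replicate 3 apart.

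The 3 mutants shared a shift away from WT, for which tissue share, a strain variant and the shared controls were weighed but no effect of the mutations themselves was tested. Independent noise in the shared WT arrays would not make these arrays alike. WT arrays correlated at 0.981 to 0.984 with each other and at 0.962 to 0.978 with mutant arrays, which argues against such noise as the whole cause. A difference common to the WT samples other than genotype, such as a batch, would look the same and remains open. The lowest covariance of the changes was 0.09, and 0.0609 without asp1-10 replicate 3. Simulations of unchanged groups with independent genes reached at most 0.0199 and 0.0177. Measured genes vary together, with an estimated correlation of 0.685 among the ribosomal genes, so unchanged groups could reach covariances above the simulated ones. Without that array the correlations of asp1-10 with the other mutants, 0.481 and 0.505, lay near the simulated 0.446 and 0.447, so part of the shared shift of asp1-10 rests on it. Less bract tissue in the mutant samples could raise meristem transcripts together, but the highest median of the CLAVATA and WUSCHEL genes, 0.371, rested on 2 genes and could not decide. The photosynthesis list, fixed beforehand as a marker of green bract and leaf tissue, had means of -0.729, -0.496 and -0.667 in fon2-3, asp1-10 and the double mutant. Less bract tissue would lower these genes too, so their falls cannot be told apart from effects of the mutations. A strain variant that acts on adjacent genes would put shared genes side by side, but 2 neighbouring pairs were seen among 160 genes (assembly ASM3414082v1), and 49.4% of random draws had as many. A variant that acts on distant genes would leave no such pairs, so a strain variant remains open.

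ASPR2 was higher in both lines with an asp1 allele. Array normalization is an unlikely cause, since the lower of its 2 changes was 2.07 with the other scalings. A strain variant remains open: 0 of the 20 nearest measured genes of ASPR2 were called in both lines, but a variant at ASPR2 itself would leave its neighbours unchanged. A tissue or stage difference shared with fon2-3 would raise it there too, but asp1-10 exceeded fon2-3 by 1.89, a difference that stayed between 1.61 and 2.13 under 16 alternatives and passed in 5. Cross-hybridising RNA of a paralog remains open, as ASPR1 differed from WT by 0.0111 in asp1-10 and ASP1 was not analysed here under its name. With the paralog left open, these arrays did not decide whether the loss of ASP1 function raises ASPR2, which restoring ASP1 in asp1-10 would test.

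Results were picked out here because an effect differed between groups in a direct test, and they follow as values. The 7 probes departing from additivity included those of LOC4326339 (2.74), LOC4340483 (-1.297), LOC4341846 (-1.07) and LOC4344111 (-1.475). The 6 probes differing between asp1-10 and fon2-3 included those of ASPR2 (1.89), LOC4333361 (-1.32) and LOC4335004 (-2.02).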

How the results depend on the processing

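No called named gene turned its direction with cyclic loess, centring, fits of only the groups compared, the block or a left-out array, and no called list did with an estimated correlation, fry, dim probes left out, cyclic loess, the block or a left-out array, but counts moved by large factors. Among genes not called, the change of ASPR2 in fon2-3 ran from -0.04 to 0.49 and that of ASPR1 in asp1-10 from -0.03 to 0.04. Counts are given for fon2-3, asp1-10 and the double mutant against WT, the double mutant against fon2-3 and against asp1-10, additivity, asp1-10 against fon2-3 and the F-test, where they moved by more than 1.5 times from the 2866, 1157, 2358, 5, 8, 7, 6 and 973 above. Centring each array on its median moved no count that far, and counts not given under another alternative stayed within that factor. Leaving out dim probes gave 4718, 2507 and 4191 against WT, 14 for the double mutant against asp1-10, 22 for additivity, 41 for asp1-10 against fon2-3 and 2790 for the F-test; it called 2 lists in fon2-3, 3 in the double mutant against fon2-3 and 1 in asp1-10 against fon2-3, and the correlation of fon2-3 with double mutant changes was 0.88. Array weights gave 4421 for fon2-3, 4192 for the double mutant, 13 for asp1-10 against fon2-3 and 2762 for the F-test; the lowest weight, 0.563, was that of asp1-10 replicate 3. An absolute log2 change of at least 1 left 1134, 496 and 989 against WT and 603 in the F-test. With 1 probe per named gene there were 1410, 766 and 1138 against WT, 4 for the double mutant against asp1-10, 36 for additivity and 30 for asp1-10 against fon2-3. Fitting only the groups compared gave 2 for asp1-10 against WT, 2 for the double mutant against fon2-3, 3 for it against asp1-10 and 1 for asp1-10 against fon2-3. The variance trend with a robust prior gave 1775 for asp1-10, 12 for additivity, 22 for asp1-10 against fon2-3 and 1917 for the F-test. Cyclic loess gave 4 for additivity and 14 for asp1-10 against fon2-3 and called 0 lists in fon2-3. Identical probes counted once, an alternative chosen after the data were seen, gave 15 for additivity and 23 for asp1-10 against fon2-3. An estimated correlation called 0 lists in fon2-3, asp1-10 and the double mutant against WT, 0 in the double mutant against asp1-10 and 0 in asp1-10 against fon2-3, whereas fry called 2, 2 and 10 lists against WT. Over genes past the F-test the correlations between mutants were 0.814, 0.902 and 0.866. The cause of these differences was not tested.

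With replicate number as a block the counts were 1475, 508 and 1147 against WT, 2 for the double mutant against fon2-3, 4 against asp1-10, 2 for additivity, 1 for asp1-10 against fon2-3 with 0 lists called, and 304 in the F-test. The numbers did not pair the samples: 2 of 18 pairs of arrays with the same number had residuals correlated above 0.1, with r from -0.182 to 0.106.

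Leaving out 1 array at a time gave 1 to 4554 probes in fon2-3, 163 to 1202 in asp1-10 and 18 to 3998 in the double mutant against WT, 2 to 8 in the double mutant against fon2-3, 4 to 100 against asp1-10, 1 to 25 for additivity, 1 to 300 for asp1-10 against fon2-3 and 20 to 2978 in the F-test. Lists called ranged from 0 to 1, 1 to 2 and 0 to 5 against WT, 0 to 3 in the double mutant against fon2-3, 4 to 5 against asp1-10, 0 to 0 for additivity and 0 to 2 in asp1-10 against fon2-3. The balance of direction turned in the double mutant against asp1-10 from 7 higher and 1 lower to 26 and 74 without asp1-10 replicate 3, and in asp1-10 against fon2-3 from 1 and 5 to 14 and 7 without fon2-3 replicate 2 and 153 and 147 without asp1-10 replicate 3. For additivity, where 2 lay upward and 5 downward, most fits with 1 array left out kept 1 upward probe and 0 downward. Correlations ranged from 0.481 to 0.77 (fon2-3 with asp1-10), 0.806 to 0.874 (fon2-3 with the double mutant) and 0.505 to 0.785 (asp1-10 with the double mutant).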

Other observations

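Probes without a listed gene held some of the clearest differences between genotypes, and they were picked out after their values had been seen. Probe 15869015 read 4.31 (SD 0.28, n = 3) in WT and 4.72 (SD 0.0508) in asp1-10, against 7.85 (SD 0.4) in fon2-3 and 8.07 (SD 0.119) in the double mutant, so it was high in both lines with the fon2-3 allele. Probe 15861060 read 8.68 (SD 0.388) in the double mutant against 6.33 (SD 0.23) in asp1-10 and 6.40 (SD 0.235) in WT, with fon2-3 between them at 7.675 (SD 0.188) (adjusted p = 0.00209 between the double mutant and asp1-10 in limma). Probe 15876607 read 7.16 (SD 0.112) in the double mutant against 5.90 (SD 0.174) in WT, 5.88 (SD 0.202) in fon2-3 and 6.305 (SD 0.135) in asp1-10. Probe 15803623 read 9.10 (SD 0.189) in fon2-3 and 9.23 (SD 0.0311) in asp1-10 but 8.31 (SD 0.244) in WT and 8.25 (SD 0.111) in the double mutant.

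LOC4326339 was high in the double mutant alone on each of its probes: the other probe read 6.29 (SD 0.397) there and below the limit for dim probes in the other genotypes, where it was not shown to exceed background. PDC2, a further pyruvate decarboxylase gene, was lower in asp1-10 replicate 3 than in the mean of replicates 1 and 2 by 2.55 log2 units, with NSHB2 lower by 3.96 and GAPC3 by 2.89.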
